A study of Homo sapiens with 10 samples.

How the data were processed

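The measurements are from 10 whole-transcript arrays, each hybridised with biotin-labelled material prepared from total RNA of a separate clone of MDA-MB-231. This is an established human triple-negative breast cancer cell line. Per the labels, 5 arrays are of clones that over-express RRP1B and 5 are of control clones. The labels also say that RNA was purified on a column with DNase digestion on that column. A terminal labelling kit for whole transcripts was used for labelling. The deposited values are log2 RMA summaries with 1 row per probe set, as the authors made them, and RMA and Partek are named, without versions, in the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays and fits probes jointly, so absolute RNA amounts are not kept, and differences of dim probe sets are compressed toward 0. The array's genome build is not given in the sources used here. No detection calls were used here, so the level at which a probe set only reads background is unknown.

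Each value column matched the title of 1 sample, and 0 columns were left unmapped. Probe sets were named from the platform annotation, with symbols looked up by Entrez ID in a RefSeq gene table of human assembly GRCh38. Of 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 had none, and only those with 1 symbol were given a gene name. In all, 557 rows repeated an earlier row exactly on all 10 arrays. The closest pair of arrays, control clones 1 and 3, differed by a root mean square of 0.22 on the log2 scale, so no array repeated another.

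The groups were compared with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3), two-sided, without covariates, on the deposited log2 values of all 10 arrays. P-values were adjusted with the Benjamini-Hochberg method over every probe set, and a probe set was called at an adjusted p under 0.05. The submitters' design text adds a fold change of at least 2.5, and that count is given too. For tests of gene groups, 35 lists were written before the data were examined, and each gene was represented by the probe set with the highest mean over all arrays, which gave 18417 genes. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 35 lists. The same test with an estimated correlation, and fry, were alternatives. Counts "adjusted over the list alone" use the Benjamini-Hochberg method within the members of that list. After the data had been examined, an exact permutation test over all splits of the clones was added for the mean of each list per clone, minus the mean of all genes. The smallest p this test can give is 0.00794. RRP1B and the spread of the clones about their group median were tested in the same way.

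Genes were named by a rule fixed before the data were examined. It takes RRP1B, and then the 12 largest positive and 12 largest negative differences among called probe sets in which all 5 clones of one group lie beyond all 5 of the other. It also takes up to 4 called members of each list by smallest p, or, where none is called, the 2 with the smallest p, as values only. Of the 12 largest negative differences, 1 is left out of the text and the figure for a reason unrelated to its values. Where a gene has several probe sets, the one with the highest mean is named.

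Genes that neighbour each other were compared after the data had been examined, in the order of the RefSeq table, with genes of the Y chromosome left out. Running medians of 31 neighbouring genes were taken over the 8356 genes with a mean log2 value of at least 9. For each over-expressing clone they were taken on the difference from the mean of the control clones, and for each control clone on the difference from the other control clones. A shared block is a run of at least 10 windows beyond 0.25 in all 5 over-expressing clones and in none of the control clones. As an alternative, the median deviation of the 30 nearest genes was subtracted from each gene on each array before the fit.

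The tests were run on simulated data, drawn for the real probe sets from their means and their spread within groups. In the simulation of over-expressing against control clones over 33297 probe sets, 62.0% of those changed by 0.5 on the log2 scale and 86.0% of those changed by 1 were called, with 10 false calls. With none changed, 0 were called. A list raised by 0.3 was called among the 35 lists of 18417 genes, with 0 false calls. Over 8356 genes a block raised by 0.5 was found, with 0 blocks found where none was added, and its median fell from 0.50 to 0.06 after the local correction. The exact test gave the raised list p = 0.00794 but an adjusted p of 0.278, so it cannot pass a list that stands alone among 35. All called genes of a raised block lay in windows of 51 genes shifted in their own direction, against 3.54% of all genes with no block raised. The simulation draws genes independently, so it does not test what correlated genes do to a list test or to the count of blocks. Without correlated neighbours, 0 blocks where none was added could hardly have come out otherwise. Blocks raised by less than 0.5 were not simulated.

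Alternatives covered another normalization, centring, filters on dim and on unnamed probe sets, array weights, the variance model, the thresholds, other set tests and leaving out each clone in turn. A filter at a mean of 8, counting identical rows once, leaving out both clones numbered 5, the exact test of lists and the local correction were added after the data had been examined. The number of arrays limits the precision of every value. Nothing in the labels says how the clones were derived or whether they come from separate transfections, so p-values measure the spread between these clones only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.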

Results

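Expression was measured in 10 clones of MDA-MB-231 cells, 5 of which over-express RRP1B and 5 of which are control clones. MDA-MB-231 is a human triple-negative breast cancer line that grows invasively and spreads in mice. RRP1B is a nucleolar protein related to the ribosomal RNA processing factor RRP1, and germline variation in it has been linked to metastasis of breast cancer. The over-expressing clones carry the numbers 5, 7, 8, 9 and 10, and the control clones the numbers 1, 3, 4, 5 and 6. Each clone was measured on 1 whole-transcript array, and the array medians ran from 7.92 to 8.05 on the log2 scale.

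RRP1B itself was higher in every over-expressing clone than in every control clone. Its probe set (8068902) averaged 12.02 ± 0.35 (SD, n = 5) in the over-expressing clones and 10.49 ± 0.11 (SD, n = 5) in the control clones. The difference of 1.53 ± 0.15 (SE) on the log2 scale is 2.88-fold, with an adjusted p of 3.26e-05 in limma. Over-expressing clone 10 had the highest value, 12.63, and the other over-expressing clones lay between 11.76 and 11.97. The control clones lay between 10.38 and 10.67. The exact two-sided permutation test gave p = 0.00794, the smallest value that 5 against 5 clones allow. Other genes changed more, since 68 probe sets had a larger positive difference than RRP1B.

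**Figure D1:**
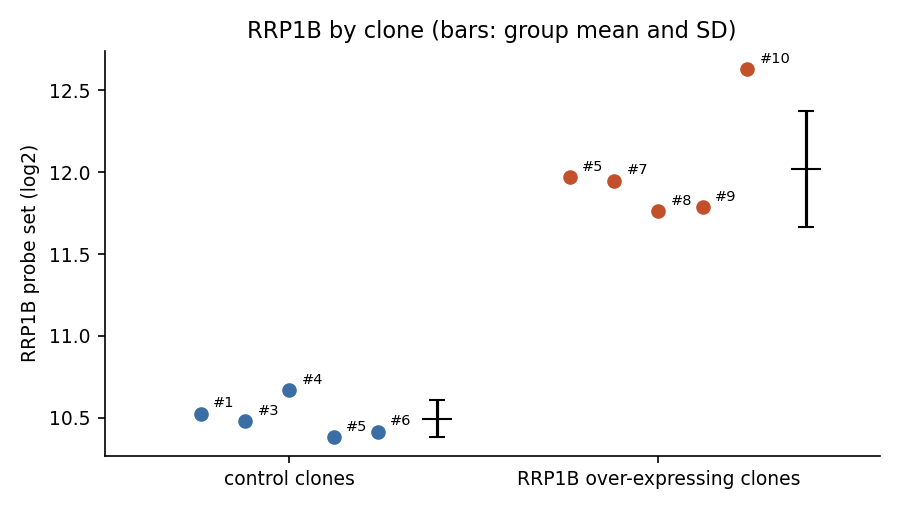
The vertical axis is the log2 value of the RRP1B probe set, and each point is 1 clone, marked with its number, beside a bar for the mean and SD of its group of 5. The over-expressing clones sit between 11.76 and 12.63 and the control clones between 10.38 and 10.67, so the groups do not overlap.

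The comparison of the groups asks which genes differ in cells with raised RRP1B. TMEM156, a membrane protein gene, fell by 5.07 ± 0.17 (SE) on the log2 scale, a 33.5-fold difference, and MMP1, the interstitial collagenase, fell by 4.92 ± 0.36 (30.2-fold). The strongest gain was of UCA1, a long noncoding RNA, which rose by 4.22 ± 0.29 (18.6-fold). The acute-phase genes SAA2 and SAA1 rose by 3.76 ± 0.56 (13.6-fold) and 3.16 ± 0.68 (8.93-fold).

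In all, 4123 probe sets passed an adjusted p under 0.05 in limma, 1793 higher and 2330 lower in the over-expressing clones. Higher and lower were 2257 and 2329 with quantile normalization and 1738 and 1849 with median centring, so the excess of losses depends on the scaling. At the submitters' criterion of 2.5-fold, 354 remained, 95 higher and 259 lower, so that 73.2% of the large differences were losses. At 4-fold or more there were 28 higher and 108 lower. Counted as genes, 1399 rose and 1808 fell, and 75 rose and 226 fell at 2.5-fold. With 1 probe set for each of the 18417 genes, 7.55% were called higher and 9.75% lower, the shares to set beside the counts of each list below. All 5 clones of one group lay beyond all 5 of the other in 3298 of the called probe sets. Such a separation was found in 11.5% of all probe sets, against 0.794% by chance. At an adjusted p under 0.01 the count was 2307. It was 2958 without control clone 3, the lowest count with any clone left out.

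Other large losses included receptors and ligands of cell guidance and growth. ROBO1, the receptor of SLIT proteins, fell by 3.86 ± 0.10 (14.6-fold), and SEMA3A, a secreted guidance protein, fell by 4.09 ± 0.12 (17.0-fold). PDGFD, a platelet-derived growth factor, fell 13.9-fold (adjusted p = 1.07e-08). CHRDL1, an antagonist of bone morphogenetic proteins, fell by 3.83 ± 0.12, and PLXDC2, a plexin domain membrane protein, fell by 4.33 ± 0.14. The metalloprotease ADAMTS1 fell by 3.98 ± 0.13, the band 4.1-like gene EPB41L4A fell 13.9-fold, and the zinc transporter gene TMEM163 fell by 3.79 ± 0.18. MAL2, a protein of vesicle transport to the apical membrane, averaged 13.17 ± 0.08 in the control clones and 9.18 ± 1.78 in the over-expressing clones (SD, n = 5 each). It fell by 3.99 ± 0.66, with values between 7.42 and 11.66 in single over-expressing clones. The over-expressing means of EPB41L4A, PDGFD, ADAMTS1 and TMEM156 were 5.62, 6.00, 6.17 and 6.32. They lay near or below the 25th percentile of the arrays (6.14 to 6.29), where the background level is unknown. The folds of losses that reach this level, the largest fold of TMEM156 among them, are therefore uncertain.

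The largest gains were fewer and smaller. COXFA4L3, a mitochondrial protein gene, rose by 3.31 ± 0.17 (9.92-fold), and BDKRB1, the inducible bradykinin receptor, rose by 2.93 ± 0.57. The transporters SLC47A1 and SLCO3A1 rose by 2.79 ± 0.22 and 2.65 ± 0.14, and SORCS2, a receptor of the sortilin family, rose by 2.63 ± 0.13. CCDC3, PLEKHS1, LRRC61 and ZNF114 rose by 2.82, 2.78, 2.73 and 2.55. The size of some gains differed between clones. SAA2 stood at 12.60 and 13.01 in over-expressing clones 9 and 10 and between 9.97 and 10.61 in the other 3. BDKRB1 stood at 12.06 and 11.75 in clones 9 and 10 and between 9.03 and 9.38 in the others. SAA1 and SAA2 are close paralogs, and a further SAA2 probe set gave 2.53 with an adjusted p of 0.0326. UCA1 rose although it lies between FBXW9 and RAB3A, in a block of 74 neighbouring genes with a median difference of -0.39.

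**Figure D2:**
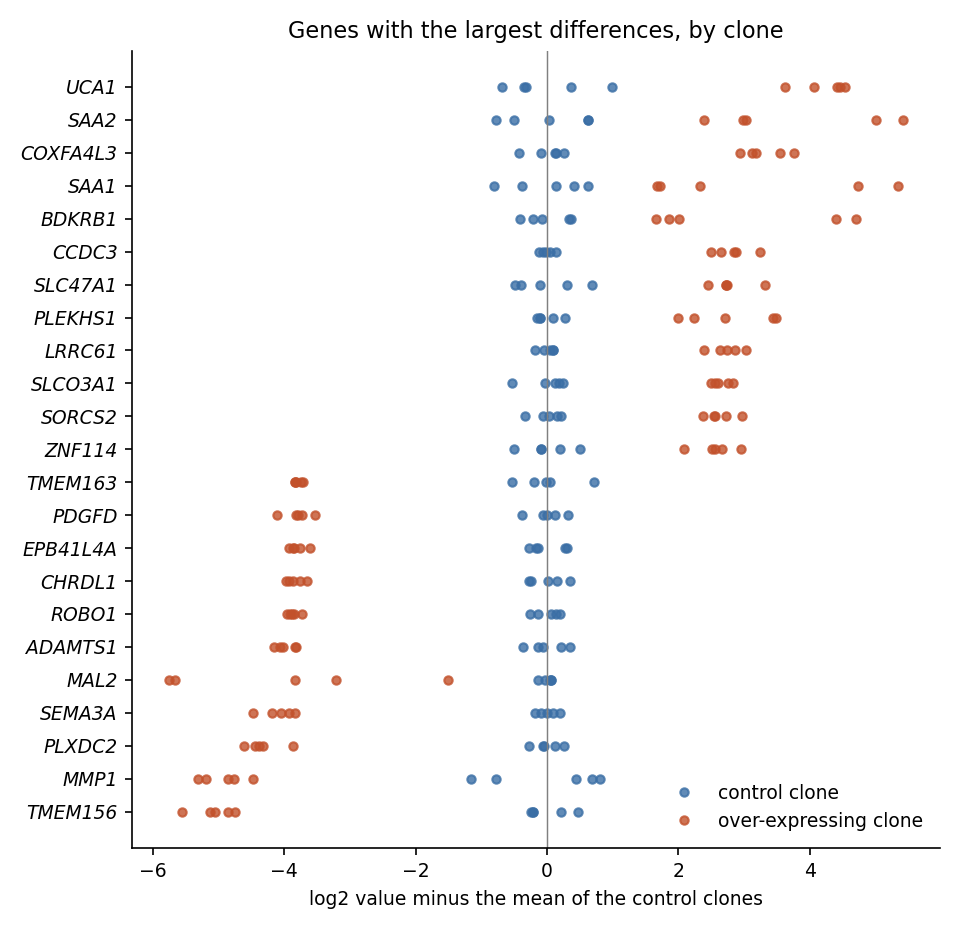
The horizontal axis is each clone's log2 value minus the mean of the control clones, for the 12 genes with the largest gains and 11 of the 12 with the largest losses (1 is not shown), and each point is 1 clone. The over-expressing clones of TMEM156 and MMP1 lie far below 0, those of UCA1 far above 0, and MAL2, SAA1, SAA2 and BDKRB1 spread most between the over-expressing clones.

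The bone metastasis list, of genes raised in sublines of MDA-MB-231 that colonise bone, fell as a group. Of its 12 genes, 9 fell and 0 rose, and the median difference was -1.05. MMP1 and ADAMTS1 belong to it, FGF5, a fibroblast growth factor, fell by 3.25 ± 0.13 (9.54-fold), and DUSP1, a phosphatase of MAP kinases, fell by 1.42 ± 0.11. CXCR4, the chemokine receptor, named here after its value was seen, fell by 2.09 ± 0.32. Adjusted over the list alone, 11 fell. The camera test gave an adjusted p of 2.15e-10 (adjusted p = 0.113 with an estimated correlation), and the exact permutation test on the clones gave p = 0.00794.

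The lung metastasis list of the same line moved apart. Of 22 genes, 6 rose and 7 fell, and 7 rose and 7 fell adjusted over the list alone. ROBO1, the glycosidase MAN1A1 (-3.77 ± 0.13) and PTGS2, the inducible cyclooxygenase (-2.82 ± 0.13, 7.06-fold), fell, and LY6E, an interferon-inducible surface protein, rose by 1.77 ± 0.09. Its camera test gave an adjusted p of 0.341. The median was -0.01 and the mean -0.58, since the losses were larger than the gains, and the mean differed between the groups in the exact permutation test (p = 0.00794).

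Targets of NRF2, the transcription factor of the antioxidant response, rose together. Of 26 genes, 16 rose and 0 fell, with a median difference of 0.45 (1.37-fold), and 18 rose and 1 fell adjusted over the list alone. The exporter ABCC3 rose by 1.91 ± 0.13 (3.75-fold), EPHX1, an epoxide hydrolase, by 1.06 ± 0.12, SRXN1, which repairs oxidised peroxiredoxins, by 0.89 ± 0.13, and the ferritin light chain FTL by 0.46 ± 0.07. The adjusted p of camera was 2.56e-07 (adjusted p = 0.401 with an estimated correlation), and the exact permutation test gave p = 0.00794.

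Genes that respond to ERK and growth factors fell. Of 27, 12 fell and 1 rose, the median was -0.28, and 14 fell and 3 rose adjusted over the list alone. The ERK phosphatases DUSP4 and DUSP6 fell by 1.37 ± 0.08 and 1.14 ± 0.11, the receptor kinase EPHA4 fell by 1.73 ± 0.15 and the feedback inhibitor SPRY2 by 0.77 ± 0.08. DUSP6 lies in a block from TMTC3 to FGD6 with a median difference of -0.34, and fell by 0.76 once the median of its 30 neighbours was removed. Camera gave an adjusted p of 3.88e-06 (adjusted p = 0.245 with an estimated correlation). The exact permutation test gave p = 0.00794.

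Camera called 6 further lists, none of them with an estimated correlation (adjusted p = 0.924 to 0.983), and the members that passed were a minority. NF-kappaB and inflammatory genes had 10 of 43 higher and 3 lower, with TNFAIP2 up by 1.32 ± 0.17 and NFKBIA, the inhibitor of NF-kappaB, up by 0.74 ± 0.10, while PTGS2 fell and IL11 fell by 1.09 ± 0.14. Over-expressing clones 9 and 10 stood highest on this list, at 0.88 and 1.07 above the control mean, and the other 3 lay between -0.03 and 0.32. S phase genes had 15 of 48 higher and 3 lower, with the replication factors GINS2 (0.72 ± 0.09), POLA2 (0.52 ± 0.08) and MCM7 (0.54 ± 0.08) up and GINS4 down by 0.80 ± 0.11. MCM7 lies in a block from BUD31 to CLDN15 whose 31 genes had a median difference of 0.32. Cholesterol synthesis genes had 4 of 25 higher and 0 lower. They were LSS (0.88 ± 0.08), EBP (0.96 ± 0.09), DHCR7 (0.45 ± 0.09) and CYP51A1 (0.30 ± 0.07). EBP lies in a block of neighbouring genes that was higher as a whole, and CYP51A1 lost its call once the median of its neighbours was removed (0.15, adjusted p = 0.156).

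Ribosome biogenesis factors, the class of RRP1B's own relatives, had 14 of 96 lower and 1 higher. UTP23, RIOK1, UTP3 and GNL2 fell by 0.68 ± 0.10, 0.61 ± 0.10, 0.66 ± 0.12 and 0.47 ± 0.09. Small nucleolar RNA genes had 23 of 176 lower and 1 higher, among them SNORD77 (-1.29 ± 0.20), SNORD78 (-0.96 ± 0.15), SNORA74A (-0.54 ± 0.09) and SNORA68 (-0.65 ± 0.10), the last of which lost its call without the shift of its neighbours (-0.24, adjusted p = 0.0709). SNORD77 averaged 4.68 in the over-expressing and 5.97 in the control clones. Both means lay below the 25th percentile of every array (6.14 to 6.29), where the background level is unknown. Splicing regulators had 7 of 48 lower and 3 higher, with HNRNPA1 and MBNL1 down by 0.53 ± 0.11 and 0.30 ± 0.06 and SRPK2 and RBM10 up by 0.37 ± 0.08 and 0.39 ± 0.09. With the shift of its neighbours removed, MBNL1 was not called (-0.15, adjusted p = 0.165) and RBM10 turned to -0.21 (adjusted p = 0.0248). The call of the splicing list held in 9 of 19 alternatives of camera. That of S phase genes ended without over-expressing clone 10 or control clone 6 (highest adjusted p = 0.0726), that of small nucleolar RNA genes without over-expressing clone 5 or control clone 1 (0.0956) and that of cholesterol genes without over-expressing clone 8 (0.0572).

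In the order NF-kappaB, S phase, cholesterol, ribosome biogenesis, small nucleolar RNA and splicing, camera gave adjusted p-values of 0.00271, 0.00879, 0.00879, 0.000304, 0.00879 and 0.0487. With an estimated correlation the adjusted p-values were 0.956, 0.983, 0.924, 0.956, 0.956 and 0.983. The exact permutation test on the clones gave unadjusted p-values of 0.0317, 0.103, 0.0159, 0.0556, 0.0873 and 0.119, and none of the 6 passed once adjusted over the 35 lists. Adjusted over the list alone, the counts higher and lower were 12 and 3, 20 and 4, 5 and 0, 2 and 23, 1 and 23, and 3 and 7. No list was called with an estimated correlation. Bone metastasis genes, NRF2 targets and ERK response genes were the 3 called lists that also passed the exact test adjusted over all lists (adjusted p = 0.0278).

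Genes of the matrix and of adhesion changed in both directions. Of 63 matrix components 11 rose and 9 fell. LUM, the proteoglycan lumican, rose by 2.28 ± 0.21 and MATN2 by 2.02 ± 0.20, while LTBP1, which binds latent TGF-beta, fell by 2.46 ± 0.13 and the collagen COL13A1 by 0.80 ± 0.07. Of 51 matrix proteases, crosslinkers and inhibitors 9 rose and 14 fell, and besides MMP1 and ADAMTS1 the membrane-bound proteases MMP14 and MMP16 fell by 0.92 ± 0.08 and 1.04 ± 0.10. Of 36 integrins and adhesion receptors 5 rose and 8 fell, with ITGA2, the collagen receptor subunit, down by 1.52 ± 0.07, ITGB8 by 1.79 ± 0.15, ITGA10 by 1.15 ± 0.12 and PCDH7 by 0.98 ± 0.12. Adjusted over the list alone, the counts higher and lower were 16 and 13, 11 and 18, and 6 and 9. Camera did not call these lists (adjusted p = 0.592, 0.152 and 0.315). The means of the protease and integrin lists fell by 0.22 and 0.11 relative to all genes and passed the exact permutation test (p = 0.00794 each). Their median differences were only -0.03 and -0.06, so large losses of single genes, such as MMP1, ADAMTS1 and ITGB8, weigh on these means.

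Markers of epithelial and mesenchymal cells did not move as opposed programmes. Among 30 epithelial markers 8 rose and 2 fell (8 and 4 adjusted over the list alone). The keratin KRT7 rose by 1.37 ± 0.18 and the tight junction genes CLDN4 and CLDN3 rose by 0.92 ± 0.09 and 0.71 ± 0.10, while CLDN7 fell by 1.25 ± 0.16. CLDN3 and CLDN4 lie together in a block from VPS37D to PMS2P3 with a median difference of 0.37. Among 27 mesenchymal markers 7 rose and 8 fell (8 and 9 over the list alone), with S100A4 and GNG11 up by 1.37 ± 0.18 and 1.17 ± 0.15 and TCF4 and MSN down by 0.75 ± 0.08 and 0.56 ± 0.07. Among 19 luminal markers 3 rose and 4 fell (5 and 5), with the prolactin receptor PRLR up by 1.93 ± 0.25 and AGR2, SPDEF and MLPH down by 1.62 ± 0.10, 1.90 ± 0.17 and 0.60 ± 0.09. Among 14 basal markers 2 rose and 1 fell (2 and 1), with TRIM29 up by 0.99 ± 0.11, LAMB3 down by 0.90 ± 0.10 and CAV1 up by 0.23 ± 0.06, a call that ended without the shift of its neighbours (0.10, adjusted p = 0.366). Camera gave adjusted p-values of 0.0936, 0.953, 0.657 and 0.657 for the 4 lists.

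Genes of other pathways changed in both directions. Several of these counts lie near or below the shares over all genes, 7.55% higher and 9.75% lower, and by themselves do not show a response of the pathway. Of 51 type I interferon response genes 16 rose and 5 fell (20 and 7 adjusted over the list alone; camera adjusted p = 0.0797, and under 0.05 without over-expressing clone 7 or 8 or control clone 1 or 4, lowest 0.0179), with IFI27, RSAD2 and IFIT1 up by 1.90 ± 0.15, 1.35 ± 0.13 and 1.02 ± 0.14 and TRIM22 down by 0.83 ± 0.12. Of 27 YAP and TEAD targets 9 rose and 3 fell (12 and 4; 0.152), with FSTL1, F3 and AJUBA up by 0.54, 0.57 and 0.31 and CCN2 down by 0.59 ± 0.08. Of 27 TGF-beta response genes 6 rose and 6 fell (7 and 8; 0.968), with ID3 and TGFBI up by 1.69 ± 0.27 and 0.81 ± 0.13 and IL11 and CCN2 down. In the ATF4 and amino acid response list 3 of 36 rose and 4 fell (5 and 4; 0.657), and without over-expressing clone 9 camera called this list (mean relative to all genes -0.20 instead of -0.10, adjusted p = 0.0195). That clone stood at 0.30 above the control mean and the other 4 between -0.28 and -0.14. PHGDH, the first enzyme of serine synthesis, fell by 1.93 ± 0.21, VLDLR fell by 1.20 ± 0.22 and VEGFA by 0.66 ± 0.08, and ATF5 rose by 0.62 ± 0.10. Hypoxia and glycolysis genes had 1 of 37 higher and 3 lower (1 and 4; 0.953), with the hexokinase HK2 down by 1.30 ± 0.22, LOX by 0.62 ± 0.13 and PFKL up by 0.43 ± 0.08. Of 33 p53 targets 4 rose and 3 fell (5 and 4; 0.690), among them PHLDA3 (0.67 ± 0.08), PMAIP1 (0.42 ± 0.07), AEN (0.40) and TP53I3 (-0.48), the calls of AEN and TP53I3 holding in 8 and 7 of the 10 fits without 1 clone.

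Few members passed in the remaining lists, none of which camera called, and in each the share that passed was below the 17.3% of all genes. E2F1 rose by 0.40 ± 0.07 as the only change among 14 RRP1B partners and its paralog (1 and 0 adjusted over the list alone; camera adjusted p = 0.880). Of 58 cytosolic ribosomal proteins 1 rose and 2 fell (0 and 2; 0.882), and these calls, FAU (0.28), RPS23 (-0.48) and RPS6 (-0.36), ended once the shift of their neighbours was removed (adjusted p = 0.504, 0.120 and 0.203 for FAU, RPS23 and RPS6). Mitosis genes had 1 of 48 higher and 3 lower (1 and 3; 0.443), with BUB3, CENPE and KIF2C at -0.39, -0.60 and -0.33 and ESPL1 at 0.29. The call of KIF2C held in 4 of the 10 fits without 1 clone and ended once the shift of its neighbours was removed (adjusted p = 0.0609), and that of ESPL1 ended without control clone 3. Replication-dependent histone genes had 0 of 44 higher and 2 lower (0 and 0; 0.657), H3C12 at -0.74 and H4C8 at -0.38, calls that held in 6 and 1 of the 10 fits without 1 clone. Chromatin silencing genes had 3 of 35 higher and 2 lower (3 and 5; 0.227), with SUV39H1 up by 0.68 ± 0.07 and DNMT3B and KDM1A down by 0.71 ± 0.10 and 0.35, the call of KDM1A holding in 3 of the 10 fits without 1 clone. SUV39H1 ends a block of neighbouring genes that was higher as a whole. UHRF1 rose by 0.68 ± 0.13, but its other probe set gave 0.01 with an adjusted p of 0.965. Unfolded protein response genes had 1 of 25 higher and 1 lower (1 and 1; 0.657), WFS1 at -0.56 and PDIA4 at 0.30, which turned to -0.05 without the shift of its neighbours. Oxidative phosphorylation genes had 3 of 61 higher and 0 lower (1 and 0; 0.657), led by NDUFB2 (0.75 ± 0.08), in the block from CEP41 to EZH2. UQCR11 and NDUFB3 rose by 0.43 and 0.44, calls that held in 4 and 1 of the 10 fits without 1 clone and ended once the shift of their neighbours was removed (adjusted p = 0.102 and 0.0525). Of 480 zinc finger genes 21 rose and 45 fell (22 and 48; 0.178, and 0.0197 without control clone 5, with a mean relative to all genes of -0.08 instead of -0.05), with ZNF521, ZNF300 and ZNF804A down by 2.92 ± 0.12, 2.11 ± 0.15 and 2.15 ± 0.17. Of 9 MHC class II genes 0 passed (0 and 0; 0.482), HLA-DPB1 having a difference of 0.65 ± 0.38 and HLA-DOA of 0.25 ± 0.12.

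Among endothelial and leukocyte markers and cancer-testis antigens, the members that passed over all probe sets fell. Of 14 endothelial markers 3 fell and 0 rose (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.0936, and 0.0470 without control clone 4), namely ESAM (-2.59 ± 0.16, 6.01-fold), KDR, the receptor of VEGF (-1.70 ± 0.17), and PECAM1 (-0.65 ± 0.06). The other PECAM1 probe set gave -0.24 with an adjusted p of 0.284. Of 19 leukocyte markers 2 fell and 0 rose (0 and 2; 0.953), LYZ (-1.55 ± 0.23) and LCP1 (-0.99 ± 0.12). Among 17 melanoma-type and cancer-testis antigens 3 fell and 0 rose (0 and 3; 0.269), MAGEC1 (-3.66 ± 0.16, 12.6-fold), MAGEC2 (-1.66 ± 0.22) and SSX1 (-1.75 ± 0.43), whose call ended without control clone 3. The median level of these lists, 6.98, 6.82 and 6.60, lay below the median of every array.

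The exact permutation test adjusted over all lists passed 10 lists, 3 higher and 7 lower. By their means, the 3 higher were NRF2 targets, mesenchymal markers and YAP and TEAD targets. The 7 lower were both metastasis lists, ERK response genes, matrix proteases, integrins, endothelial markers and cancer-testis antigens. A pass shows only that the mean of a list separates the clones, and 11.5% of all probe sets do so too. Mesenchymal markers had 7 genes higher and 8 lower. Endothelial markers and cancer-testis antigens had 3 called genes each, with medians of -0.01 and 0.01. Matrix proteases and integrins had medians of -0.03 and -0.06. Among genes with a mean of at least 9, removing the shift of neighbours led camera to call replication-dependent histone genes (23 of 44 genes, mean relative to all genes 0.18, adjusted p = 0.623 before and 0.0307 after). It also called YAP and TEAD targets (27 genes, 0.16, adjusted p = 0.110 and 0.0403) and lung metastasis genes (adjusted p = 0.0744 and 0.0318). Only 12 of the 22 lung metastasis genes were in this test, without the losses of ROBO1, MAN1A1 and PTGS2. Their mean relative to all genes was -0.02 before and 0.02 after the removal, against -0.57 over all 22. In several lists the measures of direction disagreed. The median was above 0 and the mean difference, not taken relative to all genes, below 0 for cytosolic ribosomal proteins, luminal markers, leukocyte markers, hypoxia genes and cancer-testis antigens, and the reverse held for oxidative phosphorylation. For TGF-beta response genes median and mean were above 0 and camera's direction was down.

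**Figure D3:**
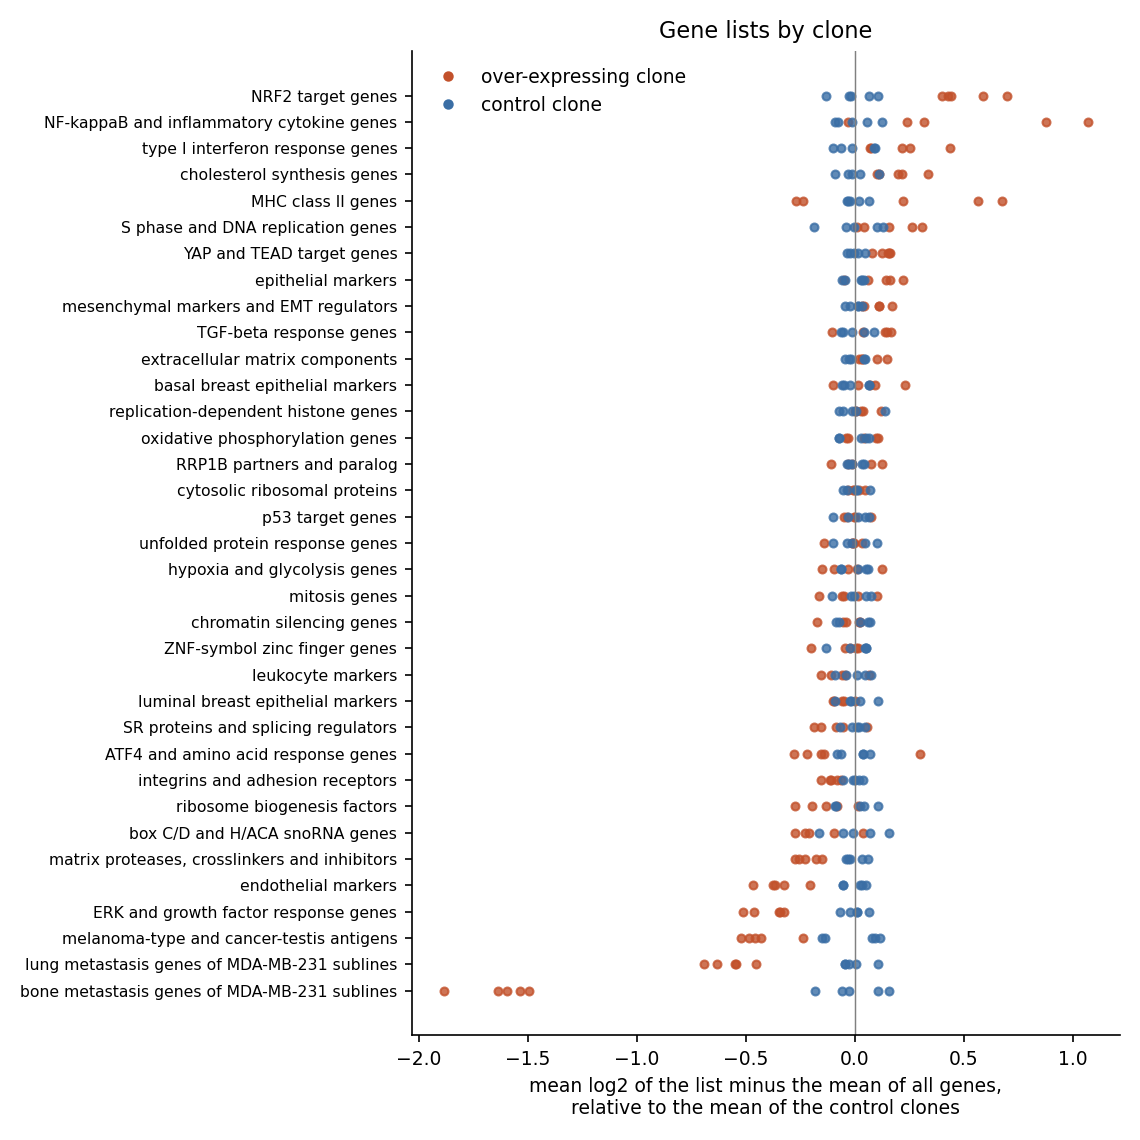
The horizontal axis is the mean log2 value of each of 35 gene lists minus the mean of all genes, relative to the mean of the control clones, and each point is 1 clone. The over-expressing clones lie apart from all control clones for 10 lists, with bone metastasis genes lowest, between -1.88 and -1.49, and NRF2 targets between 0.40 and 0.70.

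The spread of the clones within each group was compared as well. The root mean square distance from the group median was 0.22 ± 0.04 (SD, n = 5) for the over-expressing and 0.17 ± 0.03 (SD, n = 5) for the control clones. The clone spread difference of 0.0448 did not pass (exact two-sided permutation p = 0.0952). Without control clone 5 it was 0.0676 (exact permutation p = 0.0238), and without over-expressing clones 5 and 8, each left out alone, it was 0.0161 (p = 0.373) and 0.0283 (p = 0.302). Both clones numbered 5 lay farthest from their group, at 0.28 and 0.22, so leaving out either takes away the largest distance of its group. The median of a group with a clone left out also rests on fewer clones. The p-values without a clone therefore do not compare the groups on equal terms. The first principal component held 46.7% of the variance and separated the groups.

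Neighbouring genes moved together in the over-expressing clones relative to the control clones. From PUDP to SUV39H1, 73 of 75 genes were higher, 60 of them called, with a median difference of 0.59 (1.51-fold) and clone medians between 0.46 and 0.65. In the control clones the median of these genes lay between -0.13 and 0.12. From CEP41 to EZH2, 35 of 36 genes were higher, with a median of 0.60. From FBXW9 to RAB3A, 69 of 74 genes were lower, with a median of -0.39. In all, 6 such blocks with 247 genes set all 5 over-expressing clones apart from the control clones. Each control clone was compared only with the other control clones, so a change shared by all control clones would look the same. No parental line was measured, so the values cannot tell which group carries the change. Other blocks belonged to some clones. Between PRKACB and TTF2, 103 of 107 genes were higher in over-expressing clone 9 and 102 in clone 10, with medians of 0.61 and 0.53, while the other over-expressing clones lay between -0.24 and -0.03 and the control clones between -0.12 and 0.10. Of the genes with a mean of at least 9, 2701 were called before and 2607 after the median of 30 neighbours was removed, 1858 of them in both fits and in the same direction. Higher and lower were 1224 and 1477 before and 1327 and 1280 after, and at 2.5-fold 37 and 68 before and 35 and 57 after. Of the 105 called at 2.5-fold among them, 104 kept their call. Removal of a local median also centres each array, and median centring alone gave 1738 higher and 1849 lower over all probe sets. The counts by direction therefore do not tie the excess of losses to the blocks.

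**Figure D4:**
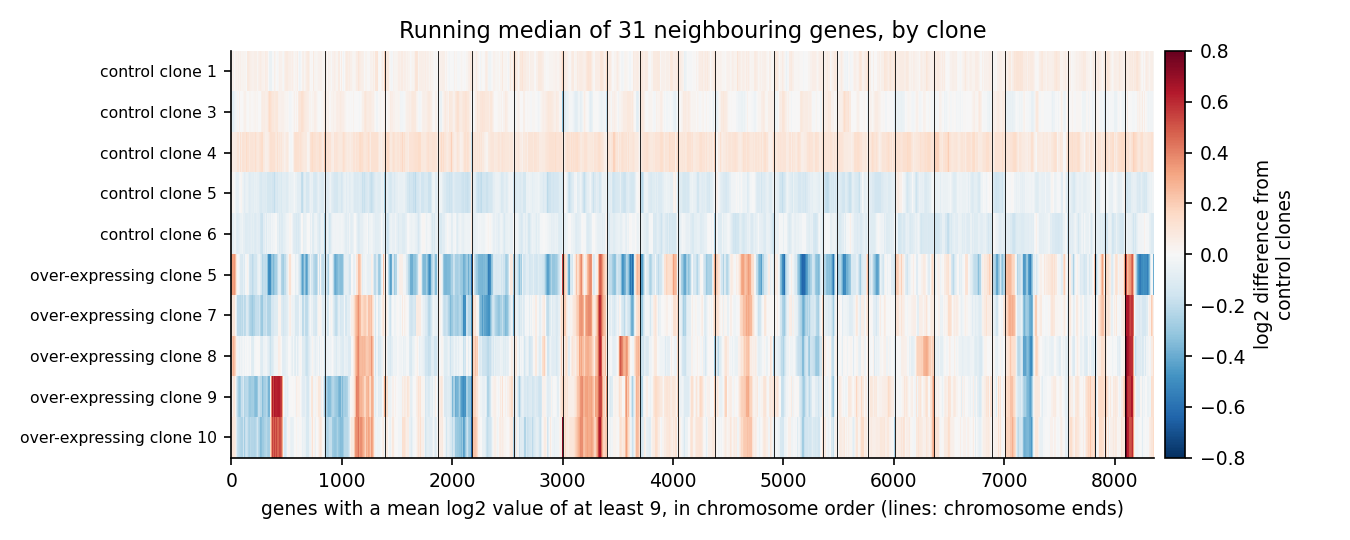
The horizontal axis holds 8356 genes with a mean log2 value of at least 9 in chromosome order, each row is 1 clone, and colour is the running median of 31 neighbouring genes as a log2 difference from the control clones. The control rows stay pale, while the over-expressing rows share blocks, among them the red block from PUDP to SUV39H1 with a median of 0.59, and clones 9 and 10 share the red block from PRKACB to TTF2. Each control row is a difference from the other control clones, so a change shared by all of them would not show there.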

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

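Neighbouring genes were compared, and the shared blocks defined, only after the data had been examined, and the tests that remove the shift of 30 neighbouring genes and the test of common ancestry were chosen after the results they bear on had been seen.

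For the number of probe sets that differ between the groups, a chance split of these arrays is argued against. Of the 126 possible splits of the 10 arrays 100 were drawn, and only 1, the real one, gave as many as 4123. The highest other gave 220. The splits treat the clones as independent, and nothing in the labels says whether they are. A shift of whole arrays is argued against by the count of 4586 after quantile normalization. Neighbouring genes account for a part, since 55.0% of the called genes lie in windows of 51 genes shifted in their own direction, against 30.2% of the uncalled genes and at most 7.57% in shuffled order, and copy number differences between the groups are a candidate explanation for this part. A shift of neighbours is not the whole cause, as 2607 genes were called after the median of 30 neighbours was removed, against 2701 before, of which 1858 (68.8%) kept their call and direction. An effect of RRP1B itself stays open as the biological explanation, and the labels give no clones in which it could be set apart from the descent of the clones.

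A chance split is also argued against, with the same limit, for the 354 probe sets at 2.5-fold. Only 1 of 100 splits, the real one, gave as many, and the highest other gave 13. The shift of 30 neighbouring genes was removed for the 105 of the 2.5-fold genes with a mean of at least 9. Of them, 99.05% stayed called in the same direction, and 89 stayed at 2.5-fold. The shared blocks had medians of at most 0.60 on the log2 scale, well below a 2.5-fold difference, so the removal could hardly end these calls. The values show only that such a shift is smaller than most of these differences. The dimmer genes among the 301 called at 2.5-fold were not tested in this way. A loss or gain of a single gene, or a change fixed in a founding cell, could still account for some of them, and the arrays hold no value that decides it.

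For the blocks of neighbouring genes shifted in all 5 over-expressing clones and in no control clone, splits of the arrays were counted too. Only 1 of 100 splits, the real one, gave as many as 6, and the highest other gave 1. The definition was made for the real groups after the data had been examined. A block shared by all over-expressing clones cannot count in another split, so this count cannot exclude chance. A shift of whole arrays left by the normalization is argued against by the 8 blocks found after quantile normalization. Copy number of these segments inherited from a common ancestor cell is a candidate explanation, and 95.5% of the genes in the blocks lie in the direction of their block. The blocks were chosen by these same values and no DNA was measured, so inheritance and an effect of RRP1B on these segments cannot be told apart. Nor do the values tell which group carries the change, since no parental line was measured.

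For the number of gene lists chance cannot be excluded, since 58 of 100 splits called at least as many as the real 9, and the highest other called 19.

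In 16 of 282 groups of 5 values, 5.67%, 1 clone stood far from the other 4, and chance gives about 1 in 20. RRP1B stood high in over-expressing clone 10, at 12.63 against 11.76 to 11.97. ID3 stood low in the same clone, at 8.932 against 10.21 to 10.68, and MAGEC1 at 6.283 against 6.65 to 6.788. In over-expressing clone 9, MBNL1 and UHRF1 stood low, at 12.05 and 11.16, and PFKL high, at 11.13. In over-expressing clone 8, WFS1 stood low at 9.392 and CYP51A1 high at 12.19, and in clone 7 EBP stood low at 11.39. In over-expressing clone 5, SSX1 stood high at 8.405 against 6.246 to 6.693, and TCF4 at 5.957. Among the control clones, UTP23 stood low in clone 5 at 10.95, TGFBI low in clone 3 at 9.476 and SNORA68 low in clone 4 at 11.83. LUM stood high in control clone 4 at 6.339 and IL11 high in control clone 1 at 9.523.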

How the results depend on the processing

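The filter at a mean of 8, the fits without both clones numbered 5 and the removal of the local shift were chosen after the results had been seen. RRP1B stayed past the threshold in all 10 other settings (1.37 to 1.56) and without each clone in turn (1.37 to 1.59). The count of called probe sets ran from 3470 to 5424 in 10 of 11 settings, and was 2307 (1007 higher, 1300 lower) at an adjusted p under 0.01, a stricter threshold. Without single clones it ran from 2958 to 4347. The count at 2.5-fold ran from 311 to 393 in 10 of 12 settings. It was 607 (195 higher, 412 lower) at 2-fold and 220, of which 143 lower, among probe sets with a mean of at least 8, where fewer were tested. Between 8 and 12 lists were called in 11 of 12 settings, with fry giving 12 and the exact test 10. Camera called 7 to 10 without single clones, and 0 with an estimated correlation. The difference in clone spread was 0.0676 without control clone 5, with a range of 0.0161 to 0.0676 over the clones left out. The cause was not tested.

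The lists of bone metastasis genes, NRF2 targets, ERK response genes, ribosome biogenesis factors and NF-kappaB genes were called in 18 of 19 alternatives of camera, those of cholesterol, S phase and small nucleolar RNA genes in 17, 16 and 16, and with an estimated correlation none was. The exact test, added later, did not call ribosome biogenesis factors and NF-kappaB genes. Relative to all genes, the mean of the cytosolic ribosomal list turned from 0.0056 to -0.00051 with quantile normalization, -0.0035 with array weights and -0.00055 without both clones numbered 5, and ran from -0.0079 to 0.023 without single clones. The mean of the p53 list turned to 0.0017 with quantile normalization and ran from -0.028 to 0.014 without single clones. The ranges without single clones crossed 0 for RRP1B partners (-0.019 to 0.040), mitosis (-0.063 to 0.0035), unfolded protein response (-0.051 to 0.0021) and hypoxia (-0.067 to 0.0027). None of these lists was called. With the local shift removed, RBM10 turned to -0.21 and PDIA4 to -0.047. In all, 18 named genes lost their call in at least 1 alternative. Removal of the local shift ended the call of 11 of the 97 named genes tested there. With median centring H4C8, FAU, NDUFB3, KDM1A, KIF2C and UQCR11 lost their call. Of these, H4C8 and KDM1A kept it in limma when the local shift was removed (adjusted p = 0.0229 and 0.0430). No paired analysis was possible because no label links a clone of one group with a clone of the other. No detection calls were used, so the signal over background of dim probe sets is unknown.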

Other observations

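The comparisons of single clones in this part were chosen after the results had been seen. Over-expressing clones 9 and 10 stood apart from the other over-expressing clones on several genes. Besides SAA1, at 11.79 and 12.40 against 8.73 to 9.39, and BDKRB1, they share the block from PRKACB to TTF2. HLA-DPB1, a class II antigen presentation gene, stood at 11.82, 12.19 and 12.17 in over-expressing clones 5, 9 and 10 and at 10.13 and 10.34 in clones 7 and 8. RRP1, the paralog of RRP1B, had a difference of 0.24 with an adjusted p of 0.0654.

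The share of windows of 31 genes shifted by more than 0.25 was 12.4%, 7.64%, 15.1% and 12.8% in over-expressing clones 7, 8, 9 and 10. It was highest in over-expressing clone 5, with 25.8% of the windows lower and 5.24% higher. With gene order shuffled, 3.88% of the windows of clone 5 lay beyond the same limit, against 0.120% to 0.419% in the other over-expressing clones, so a part of its share is not tied to gene order. In the control clones it lay between 0.0239% and 0.132%, and the control reference differs, since each control clone was compared with the other control clones.

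A hypothesis is that the over-expressing clones descend from 1 cell that carried the shared blocks, and that clones 9 and 10 parted from the others later. The 95.5% of block genes in the direction of their block may reflect this, but the blocks were chosen by these values, and DNA copy number of each clone would be needed to test it. Without a parental line the values also cannot tell whether the over-expressing or the control clones carry the change.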
